A study of Mus musculus with 6 samples.

How the data were processed

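RNA was profiled on Affymetrix whole-transcript arrays in macrophages drawn from the mouse peritoneal cavity 4 days after an injection of thioglycollate, an irritant that recruits macrophages. Per the labels' protocols, the cells came from C57BL/6J Tet2-/- mice and wild-type littermates and were plated without treatment. Per the same protocols, total RNA was extracted 10 h later. The 6 arrays were made from 3 samples per genotype, which the labels call biological replicates and number 4, 5 and 6. The labels do not say outright that each replicate is a separate animal, so p-values measure the spread between these samples.

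The sample title and the genotype characteristic contradicted each other for 4 of the 6 samples. Groups were taken from the title, since it gives genotype and replicate number together and each genotype then holds replicates 4, 5 and 6 once. By the characteristic, one group would hold replicate 5 more than once. The characteristic was used as an alternative grouping. The design text speaks of inflammatory stimuli, whereas the titles and the treatment protocol name none.

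The deposited table holds log2 expression values for 25206 probe sets, made with RMA in affy 1.36.1 per the submitters' processing notes. RMA corrects background, normalizes arrays by quantiles and summarises probes on a log2 scale. The log2 scale was read from the range of the deposited values and from that method, and is not stated in the sources used here. Whether the 6 arrays were normalized together is also not given in the sources used here, and their deposited medians ran from 2.77 to 2.93. The array scanner files and the probe definition were not used here, so background levels per probe set could not be checked. RMA compresses differences near the background, so fold differences of dim genes may be understated. The number of arrays, 3 per group, limits the precision of every value.

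Probe sets were named through the platform's annotation, which gave 1 gene for 23185 and several for 0, and 2021 probe sets stayed unnamed. All 23185 named probe sets were found by gene identifier in the RefSeq table of assembly GRCm38.p6, and 0 symbols needed an update. That table served for names and for which genes neighbour each other, and no coordinates are given because the array values name no genome build.

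Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on the deposited log2 values over all 25206 probe sets, without a covariate. P-values were adjusted with the Benjamini-Hochberg method and a threshold of 0.05 was used. The 34 gene lists, with 587 different genes of which 536 were measured, were tested with limma's camera at a preset inter-gene correlation of 0.01. A listed gene was matched by its current symbol, then by an older symbol that no other gene carries. Lists needed at least 5 measured genes, and adjustment ran over the 34 lists. The camera test with an estimated correlation and the fry test were alternatives. Fry's directional test asks whether a list's genes move one way on balance, and its mixed test asks whether they move in either direction.

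The test, the grouping, the gene lists, the other settings and the rule for named genes were chosen before the data were examined. The rule took Tet2, Tet1 and Tet3, and the 12 genes with the largest positive and the 12 with the largest negative difference. These places were filled from genes with an unadjusted p under 0.01 where too few passed the threshold. It also took up to 4 members of each list with the smallest p, the sex chromosome genes, and genes past the threshold near Tet2. Other list members and genes called without one array were named after their values were seen.

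The scripts were tested on simulated data of the same size and spread, with 200 genes of the brighter probe sets changed. The simulated Tet2-/- against wild-type test over 25206 probe sets recovered 4.48% of genes changed by 0.5 log2 units. It recovered 91.0% of those changed by 1 and 100% of those changed by 2. It called 14 of 25006 unchanged genes. These shares hold for 200 changed genes. With fewer changed genes the Benjamini-Hochberg cutoff would be stricter, so they do not give the recovery in the data. There Itgax, at a difference of -1.49, did not pass (limma adjusted p = 0.197). In the simulated test of the 34 lists, 5 of 5 lists shifted by 0.3 log2 units were recovered and 0 of 28 untouched lists were called. Simulated genes varied independently, whereas members of some lists varied together in the data (estimated correlation up to 0.666). The simulation therefore does not check camera's calls of correlated lists.

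The other settings were the grouping by characteristic, the replicate number as a block, an intensity trend with robust variances, array weights, median-centred arrays, a further quantile normalization, the brighter part of the probe sets, other thresholds, other set tests and leaving out each array. A block for the first and last 3 arrays of the deposit was added after seeing the data.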

Results

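The series measured steady-state RNA in thioglycollate-elicited peritoneal macrophages from mice lacking Tet2 and from wild-type littermates, without added stimulus. Tet2 encodes a dioxygenase that oxidises 5-methylcytosine in DNA. The comparison asks which macrophage transcripts differ when Tet2 is absent. Each group held 3 arrays, labelled replicates 4, 5 and 6. Median log2 expression per array lay between 2.77 and 2.93, and the interquartile range between 2.99 and 3.33. The array labelled Tet2-/- replicate 6 had both the highest median, 2.93, and the narrowest interquartile range, 2.99. Its mean correlation with the other arrays across probe sets was the lowest, 0.982, against 0.986 to 0.989 for the other 5. No pair of arrays held the same values, and at most 2.42% of probe sets were equal in any pair.

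Tet2 transcript levels overlapped between the groups. Its log2 level was 3.96 ± 0.339 (SD, n = 3) in wild-type and 3.84 ± 0.193 (SD, n = 3) in Tet2-/- macrophages, a difference of -0.12 (95% confidence interval -0.56 to 0.32, limma adjusted p = 0.998). Without wild-type replicate 4 the difference was 0.075. Which part of the gene was deleted and where the probes of this set lie are not given in the sources used here, so the level does not check the genotype labels. Tet1, a related dioxygenase, was near the low end of the scale in both groups and differed by 0.11, with -0.015 to 0.30 when single arrays were left out. Tet3, the third family member, was at 5.78 ± 0.0252 (SD, n = 3) in wild-type and 5.43 ± 0.205 (SD, n = 3) in Tet2-/- cells, a difference of -0.34 that did not pass (limma adjusted p = 0.998). Dnmt3a, a de novo DNA methyltransferase, differed by -0.42. The list of TET, DNA methylation and related enzymes did not pass (15 measured, mean -0.06, 6 higher and 9 lower, camera adjusted p = 0.496). Because neither Tet2 nor any other value here settles the contradicting labels, every direction below refers to the libraries labelled Tet2-/- by title.

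The 6 samples showed one sex pattern. Xist, the RNA that silences an X chromosome in female cells, lay at the low end of the scale in both groups, 1.62 ± 0.0854 (SD, n = 3) in wild-type and 1.63 ± 0.0777 (SD, n = 3) in Tet2-/-. The Y-linked Eif2s3y, a translation initiation factor subunit, was at 6.51 ± 0.202 and 6.48 ± 0.204 (SD, n = 3 each). Kdm5d, Uty, Usp9y and Tsix differed by 0.25, -0.02, -0.03 and -0.06, and Kdm5d by 0.098 without Tet2-/- replicate 5 and 0.13 without wild-type replicate 6. The list of sex chromosome genes did not pass (6 measured, camera adjusted p = 0.885).

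No single gene passed the threshold between the genotypes, although several surface receptors and enzymes of macrophages differed by more than 1 log2 unit. Itgax, which encodes the integrin CD11c, was at 6.99 ± 0.164 (SD, n = 3) in wild-type and 5.50 ± 0.244 (SD, n = 3) in Tet2-/- macrophages. That is a difference of -1.49 with a standard error of 0.164 (0.356-fold, limma adjusted p = 0.197). Ccr2, the chemokine receptor of inflammatory monocytes, was at 6.6 ± 0.145 (SD, n = 3) in wild-type and 7.98 ± 0.567 (SD, n = 3) in Tet2-/- cells, a difference of 1.38 with a standard error of 0.256 (limma adjusted p = 0.665). Plau, the urokinase plasminogen activator, was at 8.10 ± 0.175 and 6.96 ± 0.355 (SD, n = 3 each), a difference of -1.14 (limma adjusted p = 0.483). For each of these 3 genes every Tet2-/- array lay on one side of every wild-type array.

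The other genes among the 12 with the largest negative difference at an unadjusted p under 0.01 included Slc9a4, a sodium and hydrogen exchanger, at -1.49 (limma adjusted p = 0.197), and Scgb1a1, a secretoglobin, at -1.65. Tlr6, the receptor that pairs with Tlr2 to sense bacterial lipopeptides, differed by -1.24. Siglecf, a sialic acid-binding lectin of eosinophils and some macrophages, differed by -1.21. Ifi30, a lysosomal thiol reductase used in antigen processing, differed by -1.09, and Wfs1, an endoplasmic reticulum membrane protein, by -1.05. Tcp10c, 3830403N18Rik, Gm6909 and Cmbl completed the 12, with differences of -1.07, -1.07, -1.04 and -1.03. Tcp10c differed by -0.645 without wild-type replicate 6.

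Among positive differences, the cysteine protease inhibitor gene Stfa3 had the largest of the 12 named, 2.04 with a standard error of 0.285 (limma adjusted p = 0.288). Its level was 3.55 ± 0.666 (SD, n = 3) in wild-type and 5.59 ± 0.0635 (SD, n = 3) in Tet2-/- cells. Cd79a and Cd79b, the signalling chains of the B-cell receptor, differed by 1.59 and 1.55. Retnla, a secreted protein induced by interleukin-4, differed by 1.24, and Acod1, the enzyme that makes itaconate, by 1.20. Fpr2, a formyl peptide receptor, differed by 1.15. The remaining genes were Spink2 at 1.72, St8sia6 at 1.43, Ly6a2 at 1.32 (0.80 without Tet2-/- replicate 5), Cd244a at 1.20 and Tmem176b at 1.16.

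**Figure D1:**
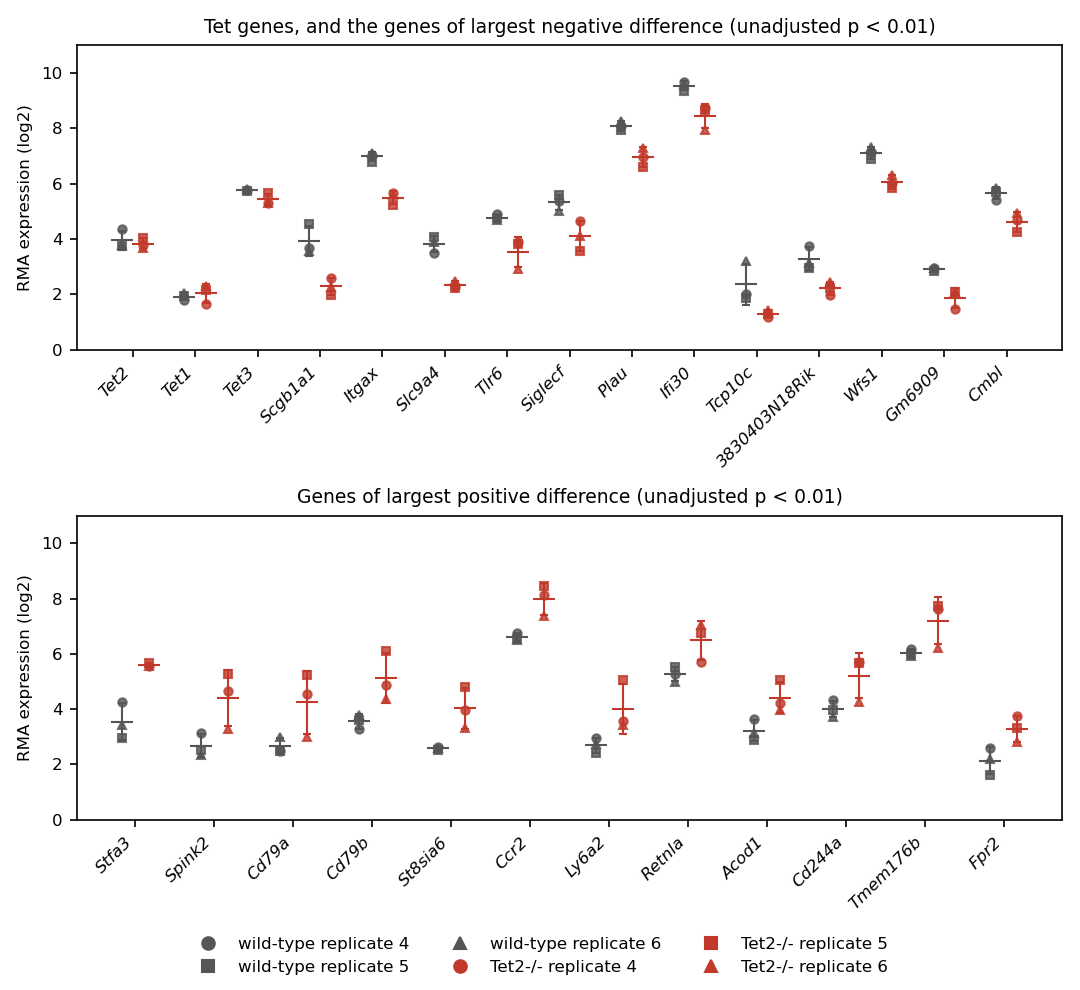
Log2 RMA expression (vertical axis) of Tet2, Tet1, Tet3 and the 24 genes with the largest negative and positive differences among those with an unadjusted p under 0.01 (horizontal axis), one symbol per array in wild-type (grey) and Tet2-/- (red) macrophages. Horizontal bars are means and vertical bars SD over 3 arrays; Itgax lay at 6.99 in wild-type and 5.50 in Tet2-/-, and in Cd79a and Tmem176b the Tet2-/- replicate 6 triangle lay nearest to wild-type.

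By limma's moderated test, 0 of 25206 probe sets passed an adjusted p of 0.05 and 0 passed 0.1, the smallest being 0.197. At an unadjusted p under 0.05 there were 910 probe sets (431 higher and 479 lower in Tet2-/-), fewer than the 1260 that chance gives. At p under 0.01 there were 202 (84 higher, 118 lower), and 665 without Tet2-/- replicate 6, 117 without wild-type replicate 5 and 124 without wild-type replicate 6. The 3 arrays of one group lay wholly above or below those of the other for 7.36% of the 23185 named genes, where chance gives 10%. Without Tet2-/- replicate 6 the count past the threshold went from 0 to 19, without wild-type replicate 4 it was 1 (Stfa3), and with array weights it was 2 (Itgax and Slc9a4).

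Genes of the resident large peritoneal macrophage rose as a list in the Tet2-/- libraries (17 measured, mean log2 difference 0.60, median 0.56). Of these, 14 were higher and 3 lower, and camera gave an adjusted p of 2.25e-06 (adjusted p = 0.879 with an estimated correlation). None of its members passed over all genes or adjusted over the list alone. The member with the largest difference was Alox15, a lipoxygenase of resident peritoneal macrophages, at 2.08 with a standard error of 0.680. Icam2, an adhesion molecule, differed by 1.06 (1.61 without Tet2-/- replicate 6), Cd5l, a secreted scavenger receptor protein, by 0.74, and Timd4, a receptor for dying cells, by 0.56. Gata6, the transcription factor that specifies this cell, differed by 0.35. The shift did not run through all 3 Tet2-/- arrays: relative to the mean of the 6 arrays, the list stood at 0.56 and 0.82 in replicates 4 and 5 and at -0.48 in replicate 6. Wild-type arrays stood at -0.04, -0.52 and -0.34. The list mean was 0.99 without Tet2-/- replicate 6, 0.34 without Tet2-/- replicate 5 and 0.34 with the first 3 and the last 3 arrays of the deposit as a block (the deposit block).

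The monocyte and small peritoneal macrophage list also rose (12 measured, mean 0.38, 8 higher and 4 lower, camera adjusted p = 0.0199, adjusted p = 0.879 with an estimated correlation). Its median was only 0.08, so the shift came from a few members. Besides Ccr2, which passed adjusted over the list alone, these were Plac8, a monocyte and lymphocyte gene, at 1.77, the fractalkine receptor Cx3cr1 at 1.11, and the monocyte surface marker Ly6c2 at 0.53. Replicate 6 again stood apart, at -0.15 against 0.23 and 0.49 in Tet2-/- replicates 4 and 5. The call was lost without Tet2-/- replicate 4 (adjusted p = 0.129), Tet2-/- replicate 5 (0.126) or wild-type replicate 5 (0.142), on ranks (0.304) and with the deposit block (mean 0.26, adjusted p = 0.142). Without Tet2-/- replicate 5 the list mean was 0.23 and the Plac8 and Ly6c2 differences 0.92 and 0.35, and Ly6c2 was at 0.80 without Tet2-/- replicate 6.

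The list of MHC class II and co-stimulation genes rose by camera's test: of 11 measured, 10 were higher and 1, Cd80, was lower (mean 0.36, camera adjusted p = 2.08e-05, adjusted p = 0.879 with an estimated correlation). None passed singly, over all genes or adjusted over the list alone. H2-DMb2, a chain of the peptide-loading chaperone, differed by 1.42 and the class II chain H2-Aa by 0.64 with a standard error of 0.184. Differences of 0.23 and 0.27 were measured for H2-Eb1 and the co-stimulatory ligand Cd86. Ciita, the master regulator of class II transcription, differed by 0.35. The list stood at 0.20 and 0.45 in Tet2-/- replicates 4 and 5 and at -0.11 in replicate 6, against -0.17, -0.20 and -0.16 in wild-type. Without Tet2-/- replicate 5 its mean was 0.22 and the H2-DMb2 difference 0.79.

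Markers of B cells, another cell type of the peritoneal cavity, moved with it. Of 13 measured B-cell genes, 12 were higher (mean 0.53, camera adjusted p = 0.000157, adjusted p = 0.879 with an estimated correlation). Cd79a, Cd79b and Cd22 passed adjusted over the list alone and 0 passed over all genes. The B-cell surface antigen Ms4a1 differed by 1.07 and the immunoglobulin heavy chain gene Ighm by 0.95. The exception was Cd22, an inhibitory receptor, which was at 6.14 ± 0.0702 (SD, n = 3) in wild-type and 5.34 ± 0.142 (SD, n = 3) in Tet2-/- cells. As for class II, the list was highest in Tet2-/- replicates 5 (0.78) and 4 (0.25). Here replicate 6 (-0.235) lay within the wild-type values (-0.34, -0.23 and -0.23), whereas for class II it lay slightly above them. Without Tet2-/- replicate 5 its mean was 0.27 and the Ms4a1 difference 0.50.

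The cell cycle list rose by camera's test, with 18 of 23 measured members higher (mean 0.25, camera adjusted p = 0.000355, adjusted p = 0.879 with an estimated correlation). None of them passed singly, over all genes or adjusted over the list alone. The mitotic kinesin Kif11 differed by 0.77, cyclin Ccna2 by 0.72, the spindle protein Nusap1 by 0.53 and the mitotic kinase Plk1 by 0.49. In this list too Tet2-/- replicate 6 stood at -0.24, below replicates 4 (0.20) and 5 (0.41), and below every wild-type array (-0.15, -0.17 and -0.050), so the shift lay in replicates 4 and 5. The call was lost without Tet2-/- replicate 5 (mean 0.10, adjusted p = 0.163) and with the deposit block (mean 0.16, adjusted p = 0.0805), and the mean was 0.43 without Tet2-/- replicate 6. Kif11, Ccna2, Nusap1 and Plk1 differed by 0.47, 0.39, 0.235 and 0.21 in that order when Tet2-/- replicate 5 was left out, and Plk1 by 0.75 without Tet2-/- replicate 6.

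**Figure D2:**
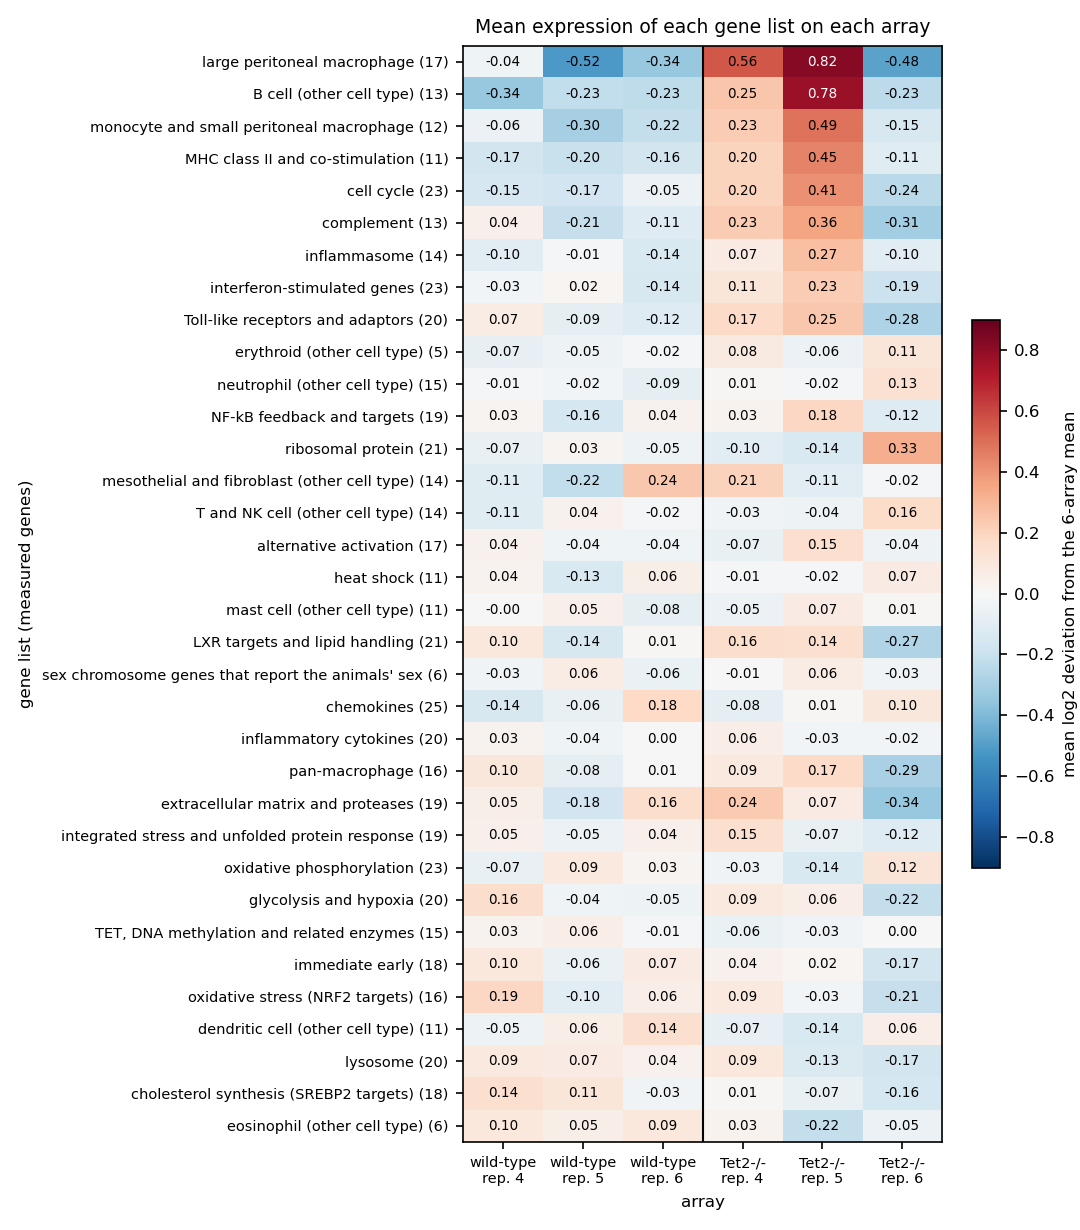
Mean log2 deviation from the 6-array mean (colour and printed value) of each of the 34 gene lists (vertical axis, measured genes in parentheses) on each of the 6 arrays (horizontal axis; wild-type left of the line, Tet2-/- right of it). The large peritoneal macrophage list stood at 0.56 and 0.82 in Tet2-/- replicates 4 and 5 and at -0.48 in replicate 6.

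Cholesterol synthesis and lysosome genes fell by a small amount as lists. Of 18 measured cholesterol genes, 15 were lower (mean -0.14, camera adjusted p = 0.00634, adjusted p = 0.879 with an estimated correlation). Among them were Mvd, which makes isopentenyl pyrophosphate, at -0.38, Sc5d, a sterol desaturase, at -0.33, Idi1, an isoprenoid isomerase, at -0.27 and Cyp51, a sterol demethylase, at -0.19. Of 20 lysosome genes, 16 were lower (mean -0.13, camera adjusted p = 0.00634, adjusted p = 0.879 with an estimated correlation). The proton pump subunits Atp6v0d2 and Atp6v1h differed by -0.46 and -0.22, the cathepsin gene Ctsl by -0.34 and the lysosomal channel Mcoln1 by -0.22. Relative to the 6-array mean, the lysosome list stood at 0.09, -0.13 and -0.17 in Tet2-/- replicates 4, 5 and 6 and at 0.09, 0.07 and 0.04 in wild-type, so replicate 4 was not below wild-type. The cholesterol list stood at 0.01, -0.07 and -0.16 against 0.14, 0.11 and -0.03. No member of either list passed singly, over all genes or adjusted over the list alone. Both calls were lost without Tet2-/- replicate 6 (adjusted p = 0.309 for cholesterol and 0.639 for lysosome), without wild-type replicate 4 (0.168 and 0.0860) and with array weights (0.278 and 0.428). The lysosome mean was -0.08 without Tet2-/- replicate 6 and -0.21 without Tet2-/- replicate 4. Leaving out Tet2-/- replicate 5 put Atp6v0d2, Atp6v1h, Ctsl and Sc5d at -0.30, -0.13, -0.21 and -0.18, and leaving out Tet2-/- replicate 6 put Mcoln1 and Cyp51 at -0.13 and -0.095. Sc5d and Idi1 were at -0.51 and -0.15 without Tet2-/- replicate 4, and Mcoln1 at -0.11 without wild-type replicate 4. When wild-type replicate 5 was left out, Atp6v1h, Idi1 and Cyp51 were at -0.10, -0.15 and -0.13.

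The inflammasome list rose slightly by camera's test, 10 of 14 members being higher (mean 0.16, camera adjusted p = 0.0298, adjusted p = 0.879 with an estimated correlation). The sensor Nlrc4 differed by 0.36, the flagellin receptors Naip5 and Naip6 by 0.40 and 0.38, and the pore-forming Gsdmd by 0.27. The differences were 0.21 for Nlrc4, 0.265 for Naip5 and 0.097 for Naip6 without Tet2-/- replicate 5, and Naip5 was at 0.19 without wild-type replicate 6. Naip5 and Naip6 were at 0.615 and 0.57 without Tet2-/- replicate 6. Nlrp3 and Casp1 differed by 0.12 and -0.07, and 0 members passed over all genes or adjusted over the list alone. The list stood at 0.07 and 0.27 in Tet2-/- replicates 4 and 5 and at -0.10 in replicate 6, within the wild-type values of -0.10, -0.0082 and -0.14. The call was lost without Tet2-/- replicate 4 (adjusted p = 0.0593), Tet2-/- replicate 5 (0.549), wild-type replicate 4 (0.165) or wild-type replicate 6 (0.0884), on ranks (0.0511), with median-centred arrays (just above 0.05) and with the deposit block (0.142). The mean was 0.07 without Tet2-/- replicate 5 and 0.26 without Tet2-/- replicate 6.

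Cytokine and chemokine genes did not pass as lists in these unstimulated cells. Of 20 inflammatory cytokine genes, 10 were higher, 9 lower and 1, Tnf, at the same mean level in both groups (camera adjusted p = 0.839). Il1b, which encodes interleukin-1 beta, was at 3.10 ± 0.301 (SD, n = 3) in wild-type and 3.85 ± 0.615 (SD, n = 3) in Tet2-/- cells, a difference of 0.75 that did not pass (limma adjusted p = 0.998) and was 0.41 without Tet2-/- replicate 5. The related Il1a and the receptor antagonist Il1rn differed by -0.43 and -0.51. Il6 differed by 0.05, and Tnf was at 5.85 ± 0.304 and 5.85 ± 0.191 (SD, n = 3 each). Of 25 chemokine genes, 10 were higher and 15 lower (camera adjusted p = 0.962). Cxcl2 and Cxcl13, attractants of neutrophils and B cells, differed by 0.85 and 0.84 (Cxcl13 by 0.525 without Tet2-/- replicate 5 and 1.305 without Tet2-/- replicate 6), Ccl1 by 0.40 and Cxcl14 by -0.78. None of these genes passed over all genes or adjusted over the list alone.

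The Toll-like receptor, NF-kB, interferon and complement lists did not pass either when all 6 arrays counted equally, without a block and as deposited. Toll-like receptors and adaptors had 16 of 20 members higher (mean 0.09, camera adjusted p = 0.0898), with Tlr2 at 0.69 and Tlr6, which passed adjusted over the list alone, at -1.24. NF-kB feedback and target genes had a mean of 0.07 (11 of 19 higher, camera adjusted p = 0.249), with the adhesion molecule Icam1 at 0.57. Interferon-stimulated genes had a mean of 0.10 (15 of 23 higher, camera adjusted p = 0.175). Complement genes had a mean of 0.19 (10 of 13 higher, camera adjusted p = 0.0691), with Cfb, the alternative pathway factor B, at 0.89 and C1s1 at 0.35. Without Tet2-/- replicate 6 all 4 of these lists passed, with adjusted p of 2.58e-05, 0.0102, 0.000200 and 2.09e-05 in that order. Their means were then 0.255, 0.141, 0.220 and 0.387. Without wild-type replicate 4 the Toll-like receptor and complement lists passed (0.0225 and 0.0318). Array weights called all 4 (0.000172, 0.0488, 0.00168 and 0.000461), and the Toll-like receptor list also passed after quantile normalization (0.0382) and on ranks (0.0313). With the block for replicate number the complement list passed (0.0326). None of the 4 passed without Tet2-/- replicate 5, where their means were -0.0072, -0.010, 0.0083 and 0.053, and Tlr2 and Cfb differed by 0.35 and 0.49.

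Alternative activation genes moved in both directions. Retnla (1.24), the mannose receptor Mrc1 (-0.59) and the lectin Clec10a (-0.92) passed adjusted over the list alone, and 0 of 17 passed over all genes. The list did not pass in one direction (8 higher, 9 lower, camera adjusted p = 0.827), while fry's mixed test, which asks for change in either direction, gave an adjusted p of 0.0180. The same mixed test passed for the dendritic cell list (adjusted p = 0.0143; camera adjusted p = 0.543). In that list Itgax passed adjusted over the list alone, whereas dendritic genes such as Zbtb46 and Flt3 differed by 0.03 and 0.09. Of the pan-macrophage genes, the lysozyme gene Lyz1 (-0.55) passed adjusted over the list alone, and Adgre1, Csf1r and Itgam differed by 0.37, 0.34 and 0.18 (7 of 16 higher, camera adjusted p = 0.553).

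Metabolic and stress lists did not pass with all 6 arrays and no block. LXR targets and lipid handling had 11 of 21 genes higher (camera adjusted p = 0.605), with the lipoprotein lipase gene Lpl at -0.31. Glycolysis and hypoxia had 11 of 20 higher (camera adjusted p = 0.839), with the glucose transporter Slc2a1 at -0.42, Pdk1 at 0.57 (0.36 without Tet2-/- replicate 5), Bnip3 at -0.55 (-0.30 without wild-type replicate 5) and Pgam1 at -1.0 (-0.47 without Tet2-/- replicate 6). Oxidative phosphorylation had 7 of 23 higher (camera adjusted p = 0.553) and ribosomal protein genes 13 of 21 (0.543). NRF2 targets had 4 of 16 higher (mean -0.10, camera adjusted p = 0.175). They passed as lower without wild-type replicate 5 (mean -0.17, adjusted p = 0.0101) and without Tet2-/- replicate 4 (mean -0.17, 0.0305). They also did with the deposit block (mean -0.17, 0.00302). Their mean was -0.018 without Tet2-/- replicate 6 and -0.028 without wild-type replicate 4. The integrated stress and unfolded protein response (9 of 19 higher, camera adjusted p = 0.553) included the transcription factor Atf3 at -0.46. Heat shock genes (5 of 11 higher, camera adjusted p = 0.996) included Hspb1 at 0.49 (0.27 without Tet2-/- replicate 6). Among immediate early genes (6 of 18 higher, camera adjusted p = 0.455), the transcription factor Egr2 (-0.86) passed adjusted over the list alone and the phosphatase Dusp1 was at -0.48. Matrix and protease genes (8 of 19 higher, camera adjusted p = 0.543) included Plau, which passed adjusted over the list alone. The matrix list passed as lower without Tet2-/- replicate 4 (mean -0.15, adjusted p = 0.0160). Its mean was 0.14 without Tet2-/- replicate 6 and 0.050 without wild-type replicate 6.

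Among marker lists of cell types other than macrophages and monocytes, only the B-cell list passed camera's test with all 6 arrays. The neutrophil list had 10 of 15 genes higher (camera adjusted p = 0.255), with the granule enzyme Mpo at 0.46. The T and NK cell list had 10 of 14 higher (camera adjusted p = 0.455), with Thy1 at 0.35, the co-stimulatory receptor Cd28 at 0.45 (0.30 without Tet2-/- replicate 6) and the interleukin-7 receptor Il7r at -0.37. The eosinophil list had 3 of 6 higher (camera adjusted p = 0.605), and of its genes only Siglecf passed adjusted over the list alone. Mast cell (0.584), mesothelial and fibroblast (0.553) and erythroid (0.496) lists gave the camera adjusted p in parentheses. Without wild-type replicate 6 the mesothelial and fibroblast list passed as higher (mean 0.19 against 0.06 with all arrays, adjusted p = 0.00381). That mean was -0.038 without wild-type replicate 5 and -0.032 without Tet2-/- replicate 4.

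Over the 34 lists, camera with the preset correlation called 8, of which 6 were higher and 2 lower. With an estimated correlation 0 held, and fry's directional test called 0 (smallest adjusted p = 0.871). For 8 lists the median and the test differed in sign, and for 3 the mean and the test did. These lists, among them cytokines, chemokines and alternative activation, were not called. With groups taken from the genotype characteristic, 0 lists and 0 genes passed.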

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

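The block for the first and last 3 arrays of the deposit was chosen after seeing the data. The count of genes past the threshold stayed at 0 under 9 alternatives. It was 2 with array weights, 202 at an unadjusted p under 0.01, and between 0 and 19 when each array was left out in turn, where 19 was without Tet2-/- replicate 6. The count of gene lists, 8, was 0 with the grouping by genotype characteristic, 0 with an estimated inter-gene correlation and 0 by fry. It was 5 to 10 when each array was left out (5 without Tet2-/- replicate 5, 10 without Tet2-/- replicate 6, of which 6 were among the 8). It was 10 with array weights, of which 6 were among the 8, 9 after quantile normalization, 7 with median-centred arrays (all 7 among the 8), 7 on ranks, of which 6 were among the 8, and 6 with the deposit block, of which 5 were. The monocyte call was lost on ranks (0.304), and the inflammasome call with median-centred arrays (adjusted p just above 0.05), on ranks (0.0511) and with the deposit block (0.142). The deposit block also ended the cell cycle (0.0805) and monocyte (0.142) calls and gave a large peritoneal macrophage mean of 0.34. Cholesterol and lysosome calls were lost with array weights (0.278 and 0.428). The cause of these changes was not tested, except that a correlation estimated above the preset 0.01 widens the test. For the 8 called lists the estimates ran from 0.082 (cholesterol synthesis) to 0.666 (large peritoneal macrophage), all above the preset value. Signal over background was not measured here, so it sets no limit that could be given.

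The replicate number as a block gave 0 genes past the threshold and 222 at an unadjusted p under 0.01, against 202 without it. It gave 9 lists, with the 8 among them, the Tet2 difference stayed at -0.12, and the added call was complement (adjusted p = 0.0326). Deviations from the group means correlated at 0.15 for replicate 4, -0.22 for replicate 5 and 0.11 for replicate 6, and not every sample correlated best with its own number. The numbers were therefore not taken to pair the samples.

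The Tet2 difference ranged from -0.23 to 0.075 when each array was left out, and was positive only without wild-type replicate 4. With groups from the genotype characteristic, the cause of the reversals being the regrouping itself, the large peritoneal macrophage list mean was -0.027 and the monocyte list mean -0.017. The cholesterol mean was 0.0037 and the lysosome mean -0.0102 with an upward test, none of them past the threshold. Under that grouping 64 of 89 named genes had the opposite sign. The log2 differences were Stfa3 -1.11, Fpr2 -0.67, Hspb1 -0.51, Cx3cr1 -0.48, Cd28 -0.46, Ccl1 -0.40, Cd244a -0.32, Spink2 -0.32, Acod1 -0.25, Ccr2 -0.25, Ly6c2 -0.25, Retnla -0.24, Alox15 -0.23, Icam1 -0.21, Icam2 -0.21, Thy1 -0.19, H2-Aa -0.15, Pdk1 -0.12, Tmem176b -0.11, C1s1 -0.10, Cd5l -0.063, H2-Eb1 -0.047, Kdm5d -0.040, Mpo -0.033, Timd4 -0.033, Nlrc4 -0.017, Il1b -0.010, Tlr2 -0.010, Dnmt3a 0.0033, Dusp1 0.013, Siglecf 0.013, Atp6v0d2 0.020, Slc2a1 0.023, Usp9y 0.027, Atp6v1h 0.030, Il1rn 0.033, 3830403N18Rik 0.060, Eif2s3y 0.060, Il1a 0.060, Lpl 0.073, Mvd 0.090, Atf3 0.11, Mrc1 0.13, Egr2 0.14, Plau 0.15, Idi1 0.15, Cxcl14 0.16, Cd22 0.19, Wfs1 0.19, Lyz1 0.21, Cyp51 0.23, Cmbl 0.25, Itgax 0.27, Tet3 0.27, Uty 0.29, Pgam1 0.30, Bnip3 0.35, Ifi30 0.40, Gm6909 0.48, Scgb1a1 0.52, Tlr6 0.53, Tcp10c 0.58, Slc9a4 0.65 and Clec10a 0.76. Leaving out single arrays reversed the sign of 6 named genes besides Tet2, some of them in the list above, with ranges of -0.065 to 0.028 for Usp9y, -0.038 to 0.050 for Xist, -0.16 to 0.028 for Tsix, -0.17 to 0.26 for Uty, -0.15 to 0.047 for Eif2s3y and -0.015 to 0.30 for Tet1. With array weights Uty was at 0.17 and Tet1 at -0.031. With median-centred arrays Xist was at -0.018. With the deposit block Usp9y was at 0.0075 and Eif2s3y at 0.083. The cause of these was not tested. Leaving out at least 1 array moved the difference by over 1.5 times for 37 of the 89 named genes, among them 27 on leaving out Tet2-/- replicate 5 and 17 on leaving out Tet2-/- replicate 6. Scaling moved the median difference of all genes by at most 0.03.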

Other observations

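The gene values without Tet2-/- replicate 6 belong to the settings listed before the data were seen. The test of a wild-type sample under a Tet2-/- label, the test of B-cell RNA as the source of the class II genes and the counts of splits for genes were chosen only after the result was seen. Without that array, limma called 19 genes (15 higher and 4 lower in Tet2-/- replicates 4 and 5 than in the 3 wild-type arrays), named after their values were seen. The higher genes included Tmem176b (log2 difference 1.65, SE 0.138, adjusted p = 0.0227) and its paralogue Tmem176a (1.43), both membrane proteins of myeloid cells. They also included Ccr2 (1.69), the tetraspanin Cd81 (1.32), the junction protein F11r (1.34), Plxdc2 (2.10) and the apolipoprotein gene Apoc2 (1.11). Alox15 (2.97) and Icam2 (1.61) belong to the large peritoneal macrophage list, and Cd79a (2.22) and Ighj4 (3.00), an immunoglobulin joining segment, to the B-cell lineage. Cd244a, Spink2, St8sia6 and Gm1966 were at 1.67, 2.28, 1.78 and 1.41. The lower genes were Itgax (-1.54), Slc9a4 (-1.57), Plau (-1.32) and G530011O06Rik (-1.16). In replicate 6 itself, Itgax (5.59) and Slc9a4 (2.5) stood near replicates 4 and 5 (5.45 and 2.25) and away from wild-type (6.99 and 3.82). Alox15 (3.74), Icam2 (5.02), Cd81 (7.51) and Plxdc2 (5.03) stood near wild-type (3.45, 5.06, 7.61 and 5.18).

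The library labelled Tet2-/- replicate 6 lay apart from replicates 4 and 5 in the large peritoneal macrophage list. A compressed range left in that array's deposited values is argued against as the source of the gap. After quantile normalization the gap was still -1.10, against -1.17 as deposited and a bound of 0.457 (2 SD of the wild-type list means). The deposited interquartile range was 2.99 on that array and 3.16 to 3.33 on the others, so this step could change little. Compression before RMA, or loss of signal in some genes only, was not tested and is not excluded. A wild-type sample under a Tet2-/- label stays open. Over 253 genes lower in replicates 4 and 5, the median position of replicate 6 was 0.304 (0 being wild-type and 1 replicates 4 and 5), and over 412 higher genes it was -0.030. Wild-type replicates 6, 5 and 4 were each left out in turn and placed on their own sets of genes. They gave 0.277 (174 genes), 0.294 (190) and 0.659 (459) for lower genes. For higher genes they gave 0.108 (276), -0.018 (252) and 0.513 (586). The bound for arguing against the label was the highest of these positions for lower genes plus their range. That bound lies past replicates 4 and 5 themselves, so the test could hardly have argued against the label. Over all probe sets Tet2-/- replicate 6 was nearer to wild-type than to Tet2-/- replicates 4 and 5, but close to neither. Its correlations were 0.982 to 0.986 with the wild-type arrays and 0.980 and 0.978 with Tet2-/- replicates 4 and 5. Wild-type arrays correlated at 0.990 to 0.991 with each other. Wild-type replicate 4 also correlated at 0.992 and 0.991 with Tet2-/- replicates 4 and 5. On the first principal component, the axis of largest spread, Tet2-/- replicate 6 stood at -41.9. Wild-type replicates 4, 5 and 6 stood at 12.1, -13.1 and -6.92, and Tet2-/- replicates 4 and 5 at 21.5 and 28.4. The first 3 arrays of the deposit (wild-type replicates 5 and 6 and Tet2-/- replicate 6) were thus all negative and the last 3 all positive. Tet2-/- replicate 6 is the only Tet2-/- array among the first 3. Its place in the deposit therefore cannot be told apart from a trait of its own, and genotype is partly mixed with that place. The position of Tet2-/- replicate 6 rests on 1 array and does not decide its label. The genotype characteristic of Tet2-/- replicate 6 also reads wild-type, but so does that of Tet2-/- replicate 4. A difference in Tet2-/- animals or in the harvest was not tested.

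B-cell and MHC class II genes were higher in the libraries labelled Tet2-/-, mainly in replicates 4 and 5. B-cell RNA in the preparations may account for the B-cell part, but stays open. A second B-cell list was written before its values were seen and shared 0 genes with the other lists. Of its 20 members, 7 were above every wild-type array in both replicates 4 and 5. Of all named genes 11.3% were (exact binomial p = 0.00468, one-sided). The binomial test takes genes as independent, whereas members of the first B-cell list varied together (estimated correlation 0.192). Replicates 4 and 5 were also the arrays where that first list was high. The p therefore does not measure spread between samples. Of the 4 members of the second list with a wild-type mean above 5, 0 were among the 7, so the count rests on dim genes. The abundant light chain gene Igkc was at 6.66 and 8.61 in replicates 4 and 5. In wild-type Igkc was at 5.02, 5.02 and 7.64, so it did not separate them. Whether B-cell RNA brings the class II genes cannot be told apart from a change within macrophages, since replicate 6 is the single Tet2-/- array without raised B-cell genes. In it the class II list was 0.068 above the wild-type mean (wild-type SD 0.020) and above every wild-type array. The B-cell list was 0.030 above the wild-type mean there (wild-type SD 0.064). The median of all probe sets was also higher on that array, 2.93 against 2.77 to 2.82 in wild-type. An offset as small as 0.068 on 1 array therefore does not show a class II rise without B-cell genes.

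The genes at an unadjusted p under 0.01 numbered 202, fewer than the 252 that chance gives. Of the 100 measured genes nearest to Tet2, 0 were among them, against 0.814% of other named genes (Fisher's exact p = 1, two-sided). At that share a count of 0 is unremarkable. The prediction for strain DNA kept around the knocked-out locus asked for most of the 202 among these 100 genes, which cannot occur. So the values place none of the 202 near Tet2, but do not decide whether strain DNA was kept there. The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. At p under 0.01, 3 of the 10 gave as many genes, the highest other being 1591; for genes past the adjusted threshold 10 of 10 gave the 0 of the titles (highest other 0), and for lists 6 of 10 gave at least 8 (highest other 15). The split with 1591 sets wild-type replicates 5 and 6 and Tet2-/- replicate 6, the first 3 arrays of the deposit, against the others, which points to a structure of the samples; with it as a block 0 genes passed and 371 were at p under 0.01, and the split by genotype characteristic gave the fewest, 41.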
